A study of Mus musculus with 18 samples.

How the data were processed

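RNA was sequenced from B lineage cells of mouse spleen in 18 libraries, 3 in each of 6 groups formed by 3 cell types and 2 genotypes. Control mice (Ctrl) carried Cd19Cre/+ alone, and knockout mice (KO) carried G9afl/fl with Cd19Cre/+, so that the G9a gene Ehmt2 could be deleted by a recombinase made in B cells. Per the labels' protocols, B220+GL7+ activated B cells and CD138+ plasma cells with low or intermediate B220 came from cell sorting of spleen 72 h after tail vein injection of 50 µg lipopolysaccharide (LPS) in 100 µl. Naive B cells were enriched with CD43 beads from uninfected mice, so cell type, LPS and isolation method changed together between naive and activated cells. Each library was made from 1000 cells with SMART-seq v4 complementary DNA and Nextera XT. Groups and replicate numbers were taken from the sample titles and genotype labels. The labels do not say that the replicates of a group came from separate animals, so the p-values measure the spread between these samples.

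The values used were the deposited RPKM values, reads per kilobase of gene and per unit of sequenced reads, which the authors computed for 12960 detected genes with 1 column per library; 0 value columns were left unused. Per the submitters' processing notes, STAR was used as a tool and mm10 as the genome build. Their versions, the gene models, the read counter, the detection criterion and the reads that made up the total are not given in the sources used here. Of the genes, 12946 were matched by Entrez identifier to RefSeq, and 24 blank or date-like symbols were restored through the same identifiers. Positions are from GENCODE M21 on GRCm38, the assembly that mm10 denotes, or from RefSeq on the same assembly where GENCODE lacked the identifier. Of 16 genes listed as immunoglobulin constant regions, 1 was tested, Jchain, which is not itself a constant region gene. Immunoglobulin constant genes and mitochondrially encoded genes (0 of 15 tested) were thus not analysed here as groups. RPKM over whole genes cannot be divided by exon, so the deleted part of Ehmt2 was not measured apart from the rest.

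Read counts were not used here. The depth of each library was estimated from the steps between the RPKM values of low genes multiplied by gene length, each step being 1 read. The estimates, in mega-reads (M), were 1.64 to 3.99 M reads in naive libraries, 2.68 to 10.76 M in activated libraries and 5.13 to 6.90 M in plasma cell libraries. They rest on gene lengths from the annotation used here, which reached 99.4% of genes, and cover counting error only. The steps were least clear in naive Ctrl libraries. There 33.0% to 35.8% of the scored values lay within 0.1 of a whole read, against 37.0% to 43.3% in the other libraries.

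RPKM values were divided by a median-of-ratios factor per library, computed over the 8012 genes above 1 RPKM in all libraries; the factors ran from 0.903 to 1.07. A gene was tested if its mean scaled RPKM reached 1 in at least 1 group, which kept 12787 genes and left out 173. Values were transformed to log2(scaled RPKM + 1), which understates fold changes of genes near 1 RPKM. All 18 libraries were fitted together with group means in limma 3.58.1 under R 4.3.3 (lmFit and eBayes with a trend, two-sided), and Benjamini-Hochberg adjusted p-values under 0.05 were called. No replicate block was used. The contrasts were KO against Ctrl within each cell type, the steps from naive to activated and from activated to plasma cells within each genotype, and the differences of the KO effect between cell types, 10 in all. The same limma test restricted to the libraries of the groups compared is called the fit of their own libraries. Tables and plots were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Adjusted p-values for genes come from limma throughout.

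The comparisons, gene lists, tests and most alternatives were fixed before the data were examined. Genes were named by rule in the KO contrasts and the Ctrl steps. They were up to 10 per direction with the largest change among called genes that reached 5 RPKM in 1 of the groups and whose groups did not overlap. Chance gives such a separation in 10% of genes for 3 libraries against 3. Numbered Gm, Rik and LOC symbols and antigen receptor segments were left out. In the contrasts between cell types, 5 genes per direction with the smallest adjusted p were named. Ehmt2 and up to 4 members of each list with the smallest adjusted p were added, and genes chosen after their values were seen are stated as such. Of the genes that the rule named, 2 are not reported here.

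Lists were tested with limma camera at a preset correlation of 0.01 between genes, which compares a list with all other tested genes, and adjusted over the 26 of 29 lists that had at least 5 tested members. They covered the G9a complex and H3K9 methylation machinery, germline genes, the plasma cell program, unfolded protein response and secretion, B cell identity, MHC class II presentation, activated and germinal centre B cells, marginal zone B cells, B-1 cells, cell cycle, p53 targets, interferon-stimulated genes, glycolysis, oxidative phosphorylation, cholesterol synthesis, Myc targets and ribosome biogenesis, trafficking and adhesion and alternative lineage transcription factors. The others were immediate early genes, cytosolic ribosomal proteins, and markers of T cells, monocytes, neutrophils, dendritic cells, erythroid cells and platelets. The NK cell list had 4 tested members and was not tested. Camera with an estimated correlation and fry were run as alternatives. Shared calls between cell types were tested with a one-sided hypergeometric test, and genes of a Ctrl differentiation step were tested with camera in a KO contrast that used none of the same libraries.

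Alternatives were RPKM as deposited, quantile normalization, a pseudocount of 0.1, no filter, a filter at 5 RPKM, a minimum of 2-fold, limma library weights, a replicate block, the fit of their own libraries, and leaving out each library in turn. A fit without the 6 naive libraries was added after their spread had been seen. The tests were tried on simulated tables in which 200 of 12787 genes were changed. In the tables used here each gene took the spread of its cell type smoothed by level, with noise independent between genes and libraries. The changed genes were drawn above a minimum level, so real data may give more false calls and a lower recovery. The fit of all libraries called 941 genes between naive groups, 755 of them false. It called 184 between activated groups and 188 between plasma cell groups, with 0 false in both. It recovered 84% and 88% of genes changed by 1 on the log2 scale in these last comparisons. The fit of their own libraries called 144 genes between naive groups with 5 false, 204 between activated groups with 4 false and 213 between plasma cell groups with 13 false. The 18 libraries held 0 identical pairs, and the highest correlation between replicates was 0.996.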

Results

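G9a, encoded by Ehmt2, is a histone methyltransferase that places mono- and dimethylation on lysine 9 of histone H3, a mark of silenced chromatin. The series asks which genes it controls as B cells differentiate, and compares naive B cells, activated B cells and plasma cells of control mice (Ctrl) with those of mice built to delete the gene in B cells (KO). There were 18 libraries, 3 per group. Values are RPKM scaled between libraries, given as mean ± SD over n = 3 libraries per group, and changes are on the log2(scaled RPKM + 1) scale with adjusted p-values from limma. Estimated depth was 1.64 to 3.99 M reads in naive libraries, 2.68 to 10.76 M in activated libraries and 5.13 to 6.90 M in plasma cell libraries. The median SD of a gene was 0.369 and 0.388 in naive Ctrl and KO, 0.134 and 0.125 in activated Ctrl and KO, and 0.133 and 0.126 in plasma cell Ctrl and KO. The median correlation between replicates was 0.926 in naive Ctrl and 0.993 in activated Ctrl.

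Ehmt2 (Entrez 110147, a protein-coding gene on the forward strand of chromosome 17 from 34898469 to 34914052, GRCm38) did not differ in RNA level between genotypes by more than the test could call. It measured 19.4 ± 7.31 in naive Ctrl and 17 ± 5.4 in naive KO, 22.3 ± 3.15 in activated Ctrl and 22.5 ± 0.817 in activated KO, and 17.2 ± 0.873 in plasma cell Ctrl against 13.8 ± 1.28 in plasma cell KO. The log2 changes of Ehmt2 were -0.16 (SE 0.22, adjusted p = 0.695), 0.02 (adjusted p = 1.000) and -0.30 (adjusted p = 1.000). In plasma cells each KO library (12.3 to 14.7) lay below each Ctrl library (16.2 to 17.8), a separation that chance gives in 10% of genes. With library weights in limma the plasma cell change was -0.28 with an adjusted p of 0.049, and in the fit of their own libraries its adjusted p was 0.110. These are values over the whole gene, and RNA from the exons left after deletion counts toward them, so the deletion itself was not checked. Its partner methyltransferase Ehmt1 measured 13.6 ± 0.935 in activated Ctrl and 14.4 ± 0.445 in activated KO. Single libraries ran from 7.48 to 16.8 in naive Ctrl and 16.2 to 23.9 in naive KO, where Ehmt1 was not called. They ran from 5.61 to 10 in plasma cell Ctrl and 7.51 to 10.5 in plasma cell KO. None of the 24 members of the list of G9a partners and other H3K9 methylation enzymes passed limma in activated or plasma cells, over all genes or adjusted over the list alone. Camera gave adjusted p = 0.158 and 0.355. In the fit of their own libraries 5 of the 24 were higher in activated KO and 0 in plasma cells, and their summed level in activated cells was 524 ± 5.83 in Ctrl and 619 ± 15.1 in KO.

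**Figure D1:**
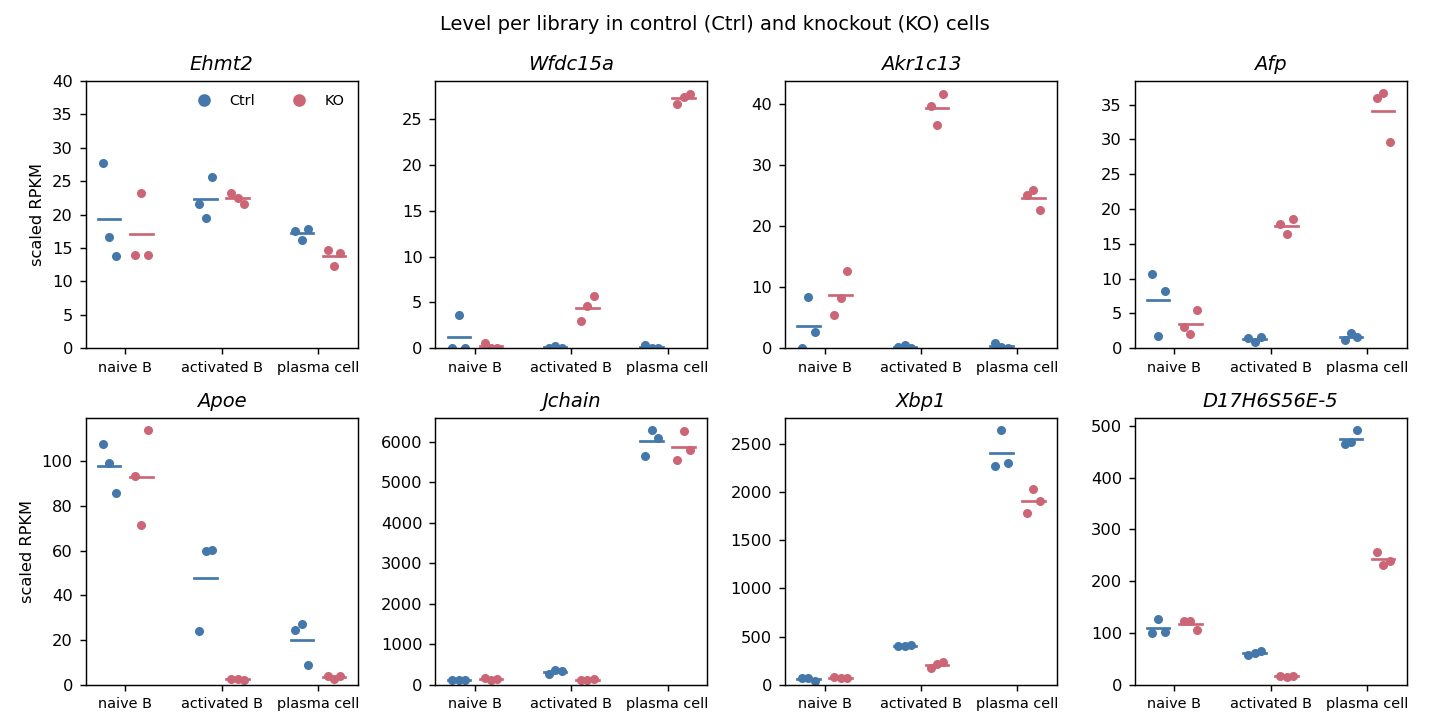
Scaled RPKM of 8 genes in each of the 18 libraries, by cell type and genotype; points are libraries and lines are group means. Ehmt2 overlaps between genotypes in naive and activated cells, while Akr1c13 in activated B cells was 0.24 in Ctrl and 39.3 in KO.

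The steps between cell types in Ctrl show what each sorted population expressed. From naive to activated B cells, cell division genes and the secretory machinery rose together. Of 62 cell cycle genes 60 rose and 1 fell, with a median log2 change of 3.11 (60 and 1 adjusted over the list alone; camera adjusted p = 3.3e-43). Ccna2, the S and G2 phase cyclin, went from 1.29 ± 1.15 to 166 ± 29.4, and Rrm2, a subunit of ribonucleotide reductase, from 3.28 ± 2.15 to 297 ± 15.8. The transcription factor Zbtb32 rose most among the named genes, from 1.22 ± 1.46 to 348 ± 14.7 (log2 change 7.51, SE 0.48, adjusted p = 1.1e-09). Xbp1, a transcription factor of the secretory program, rose from 63.4 ± 16.9 to 406 ± 9.34 (adjusted p = 2.6e-10). Of 53 unfolded protein response and secretion genes 47 rose and 4 fell (median 1.28, camera adjusted p = 6.0e-25), as did 17 of 24 cholesterol synthesis genes with 0 falling (median 1.02, adjusted p = 8.6e-09). With the correlation estimated within these libraries alone, cell cycle and secretion kept their calls (0.018 each) and cholesterol synthesis did not (0.088).

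In the opposite direction, 18 of 21 immediate early genes fell and 1 rose (median -2.08, camera adjusted p = 6.4e-08, and 0.079 with the correlation estimated within these libraries alone). The nuclear receptor Nr4a1, induced by antigen receptor signals and by tissue handling, went from 383 ± 107 to 3.87 ± 0.149. Markers of cells other than B cells were also lower in activated B cells. All 6 erythroid markers, all 8 platelet markers, all 9 T cell markers and all 5 neutrophil markers fell, with Hba-a2, an alpha globin, at 157 ± 25.8 in naive and 0.471 ± 0.369 in activated cells. Their camera adjusted p-values were 0.005, 0.002, 0.030 and 0.086, and 0.152, 0.220, 0.231 and 0.231 with an estimated correlation. Of 14 monocyte markers 9 fell and 1 rose (camera adjusted p = 0.078), and of 9 dendritic cell markers 6 fell and 1 rose (0.364). In all, 2424 genes rose and 5041 fell, 1041 and 3137 of them at least 2-fold. The median gene changed by -0.29, and by -0.06 after quantile normalization, which moved the share of higher genes from 32.5% to 48.5%. A filter at 5 RPKM moved this share to 46.7%. Low signal was higher in naive libraries, with median odorant receptor levels of 4.5 to 7.07 RPKM in naive Ctrl and 0 to 0.98 in activated Ctrl. How many of the falls rest on such signal was not tested. Naive cells were enriched with beads from uninfected mice and activated cells sorted after LPS, and the comparison cannot part these differences from cell type.

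From activated B cells to plasma cells in Ctrl, genes of antibody secretion rose and the B cell program fell. All 53 unfolded protein response and secretion genes rose (median 1.92, camera adjusted p = 3.7e-45), and of 36 plasma cell program genes 31 rose and 1 fell (median 2.61, adjusted p = 8.2e-24). Sdc1, which encodes the sorting marker CD138, rose from 1.1 ± 0.316 to 172 ± 14.3 (log2 change 6.37, SE 0.24, adjusted p = 3.2e-13). Jchain, which joins IgM and IgA units, rose from 328 ± 48.3 to 6020 ± 321, and Tnfrsf17, the survival receptor BCMA, from 0.455 ± 0.51 to 120 ± 16.7. Of 37 B cell identity genes 32 fell and 2 rose (median -2.11, adjusted p = 1.6e-25). The inhibitory receptor Cd22 went from 216 ± 19.3 to 0.868 ± 0.05 and the transcription factor Spib from 188 ± 32 to 0.724 ± 0.128. Of 16 MHC class II genes 15 fell (median -2.42, adjusted p = 8.5e-16). Zbtb32 went back to 1.82 ± 0.27 from 348 ± 14.7. These 4 lists kept their calls with an estimated correlation (adjusted p = 7.6e-05, 7.6e-05, 0.007 and 0.010). With the correlation estimated within these libraries alone none did (0.079, 0.112, 0.194 and 0.317). In total 2055 genes rose and 2141 fell, 1120 and 1073 at least 2-fold; with RPKM as deposited the share of higher genes was 34.1% in place of 49%, and the median gene changed by -0.14 in place of -0.03.

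In KO the same steps called 2717 higher and 4410 lower genes from naive to activated B cells, and 2014 higher and 2221 lower from activated B cells to plasma cells. The share of higher genes in the former moved from 38.1% to 49.3% with quantile normalization, and in the latter from 47.6% to 36.7% with RPKM as deposited.

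Activated B cells of KO mice expressed a small set of genes that control cells all but lacked, and had less RNA of the secretory machinery. Akr1c13 (Entrez 27384, chromosome 13, 4191150 to 4205596), an aldo-keto reductase, was at 0.24 ± 0.246 in Ctrl and 39.3 ± 2.54 in KO (log2 change 5.04, SE 0.51, adjusted p = 2.2e-05). Its neighbour Akr1c12 was at 0.283 ± 0.0957 and 15.7 ± 3.48 (adjusted p = 0.003), and Afp (Entrez 11576, chromosome 5, 90490737 to 90508907), the fetal liver protein alpha-fetoprotein, at 1.32 ± 0.393 and 17.6 ± 1.04 (adjusted p = 3.1e-04). Ly6c2, a surface protein of plasma cells and monocytes, rose from 14.4 ± 2.67 to 96.8 ± 3.63, Gml2 of the same gene family from 2.59 ± 0.335 to 14.2 ± 1.99, and the carbonic anhydrase Car2 from 3.84 ± 0.895 to 19.9 ± 4.17. Among the genes that fell, the lipid carrier Apoe went from 48 ± 20.8 to 2.47 ± 0.382 (log2 change -3.71, SE 0.35, adjusted p = 1.1e-05). Irf7, the regulator of the interferon response, fell from 16.9 ± 3.44 to 3.53 ± 0.719 (adjusted p = 2.2e-05), and the epoxide hydrolase Ephx1 from 20.3 ± 6.75 to 4.52 ± 1.51. D17H6S56E-5 (Entrez 110956, chromosome 17, 34996678 to 35000774), which lies near Ehmt2, fell from 61.7 ± 4.55 to 16.8 ± 0.723 (log2 change -1.81, SE 0.10, adjusted p = 1.2e-08). Akr1c12 and Akr1c13, and the Ly6c, Gml and beta globin genes, are close paralogs that could share reads.

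Of 12787 genes tested, 54 rose and 174 fell in activated KO, and 1288 had an unadjusted p under 0.05. The fit of their own libraries called 672 higher and 770 lower, which included all 228. All 228 were also called without the 6 naive libraries and with library weights. The fits that left out an activated library kept the naive libraries, whose median SD was larger. A call lost there was judged by that shared spread, and need not rest on the library left out. Fewer were called when a library was left out: 126 without Ctrl 1, 124 without Ctrl 3, 90 without Ctrl 4, 112 without KO 1, 108 without KO 3 and 165 without KO 4. The other named genes that rose were AF067061, Hbb-b2, AI427809 and Sh2d1b1, and the others that fell were Tmem52, Pltp, Hid1, Adssl1, Serinc5 and Nod1. Of these, Hbb-b2 and Sh2d1b1 lost their calls without any 1 of the 6 libraries (adjusted p up to 0.138 and 0.218), AF067061 without 4 of them (up to 0.078) and Pltp without 3 (up to 0.089). With a pseudocount of 0.1 Hid1 (limma adjusted p = 0.095), Pltp (0.211), Hbb-b2 and Sh2d1b1 lost their calls. A replicate block ended those of AF067061 (0.076), Hbb-b2 and Sh2d1b1. Over both settings the adjusted p reached 0.181 for Hbb-b2 and 0.436 for Sh2d1b1.

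The secretory genes moved as a group in activated KO. Of 53 unfolded protein response and secretion genes 16 fell and 0 rose, 31 and 0 adjusted over the list alone, with a median change of -0.37 (camera adjusted p = 8.5e-29, and 8.8e-04 with an estimated correlation). Among them the chaperone Hspa5 fell from 848 ± 57.4 to 614 ± 51.1 (adjusted p = 0.010). Its cochaperone Dnajb9 fell from 31.8 ± 1.01 to 16.4 ± 3.21 (4.6e-04) and Herpud1, of the degradation of misfolded proteins, from 228 ± 26 to 127 ± 18.2 (5.6e-04). Of 36 plasma cell program genes 5 fell and 1, Ly6c2, rose (14 and 1 adjusted over the list alone; median -0.38, camera adjusted p = 1.2e-09). Xbp1 fell from 406 ± 9.34 to 210 ± 35.6 (log2 change -0.96, SE 0.15, adjusted p = 0.002) and Jchain from 328 ± 48.3 to 127 ± 8.52 (-1.36, SE 0.11, 4.0e-06), lower in 3 of 3 KO libraries than in any Ctrl library. Prdm1, the transcription factor that drives plasma cell differentiation, measured 31.5 ± 5.43 in Ctrl and 17.2 ± 3.85 in KO, which did not pass (adjusted p = 0.220) but did in the fit of their own libraries (0.012).

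B cell genes were lower too. Of 37 B cell identity genes 5 fell and 0 rose (10 adjusted over the list alone; median -0.31, camera adjusted p = 5.7e-13). Among them were the antigen receptor subunits Cd79a, from 1390 ± 95.4 to 946 ± 91.3, and Cd79b, from 1075 ± 115 to 715 ± 37. The surface receptor Cd72 went from 173 ± 13.6 to 82.9 ± 16.4. Of 45 interferon-stimulated genes 4 fell, Irf7 and the nuclease Isg20 among them, and 1, Ifi205, rose (6 and 1 adjusted over the list alone; median -0.21, adjusted p = 7.3e-05). Ifi205 lost its call without any 1 of the 6 libraries (adjusted p up to 0.148), with quantile normalization and with a replicate block. Of 25 trafficking and adhesion genes 2 fell (4 adjusted over the list alone; median -0.31, adjusted p = 3.7e-06); S1pr1, the receptor for exit from lymphoid tissue, went from 51.2 ± 5.46 to 22.1 ± 3.71 (adjusted p = 1.0e-04). The immediate early list fell by a median of -0.36 with 2 of 21 called, and the marginal zone list by -0.25 with 2 of 22. Adjusted over the list alone 5 and 3 were called (camera adjusted p = 6.6e-07 and 2.5e-04). The 2 marginal zone genes were Pdia4 and Mzb1, which also belong to the secretion and the plasma cell program lists and are counted there too. MHC class II genes had 2 of 16 lower, and 5 adjusted over the list alone (median -0.26, camera adjusted p = 6.6e-07, and 0.058 with an estimated correlation). Of the 2, H2-Ob (limma adjusted p = 0.006) was not called without Ctrl 4 (0.053). The other, Ctss (0.036), lost its call without any 1 of the 6 libraries (up to 0.248), with RPKM as deposited and with a replicate block. The p53 and alternative lineage transcription factor lists (medians -0.03 and -0.07) were called at 0.024 and 0.031, and had adjusted p = 0.137 and 0.058 with an estimated correlation. Of their members 1 of 24, Trp53inp1, and 2 of 20, Tbx21 and Cebpb, fell (4 and 3 adjusted over the list alone). Tbx21 lost its call without 4 of the 6 libraries (up to 0.156). Each of these last lists lost its call without 2 of the 6 libraries, with adjusted p up to 0.194 and 0.061.

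Growth genes were higher in activated KO. Of 40 Myc target and ribosome biogenesis genes 2 rose and 0 fell, 21 and 0 adjusted over the list alone, with a median of 0.44 (camera adjusted p = 1.3e-23); the 2, Mybbp1a and Wdr43, lost their calls without 5 and 4 of the libraries (up to 0.226). Of 24 glycolysis genes 4 rose, 12 adjusted over the list alone with 1 lower (median 0.40, adjusted p = 7.5e-09); Tpi1 was 209 ± 21.1 in Ctrl and 320 ± 17.5 in KO and Ldha 613 ± 60.4 and 983 ± 292. In the fit of all libraries the call of each single glycolysis gene was lost without 5 or 6 of the 6 in turn, with adjusted p up to 0.350. The fit of their own libraries kept these calls. Cholesterol synthesis (24 genes, median 0.33) and cell cycle (62 genes, median 0.20) were called as lists at 2.4e-05 and 6.6e-07, with 0 members passing limma in either, both over all genes and over the list alone. The fit of their own libraries called 6 cholesterol genes higher, and 15 cell cycle genes higher and 2 lower. All lists described as changed here kept their calls with an estimated correlation (adjusted p up to 0.029) unless stated. Oxidative phosphorylation (median 0.08, 8.2e-05) did not, with adjusted p = 0.376 with an estimated correlation, and 0 of its 60 members passed. Estimated within the 6 activated libraries alone, no list stayed under 0.05, with adjusted p from 0.201 upward.

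Erythroid markers had a summed level of 15.8 ± 0.888 in activated Ctrl and 75.6 ± 8.74 in KO, from 3 of the 6 tested, while the other 3 were not higher. Called were 2, Car2 and Hbb-b2 (3 adjusted over the list alone; median 0.96, camera adjusted p = 5.8e-04, and adjusted p = 0.058 with an estimated correlation). The alpha globin Hba-a2 was at 0.471 ± 0.369 in Ctrl and 0.154 ± 0.133 in KO. T cell (median 0.14, adjusted p = 0.312), monocyte (-0.07, 0.280), neutrophil (0.10, 0.748), dendritic cell (-0.08, 0.655, where camera's direction was up) and platelet markers (-0.06, 0.548) were not called. The same held for germline genes (-0.09, 0.845, with Wfdc15a rising from 0.0867 ± 0.15 to 4.42 ± 1.36, and camera's direction up), activated and germinal centre genes (-0.05, 0.520), B-1 genes (-0.17, 0.060) and ribosomal protein genes (-0.02, 0.548).

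**Figure D2:**
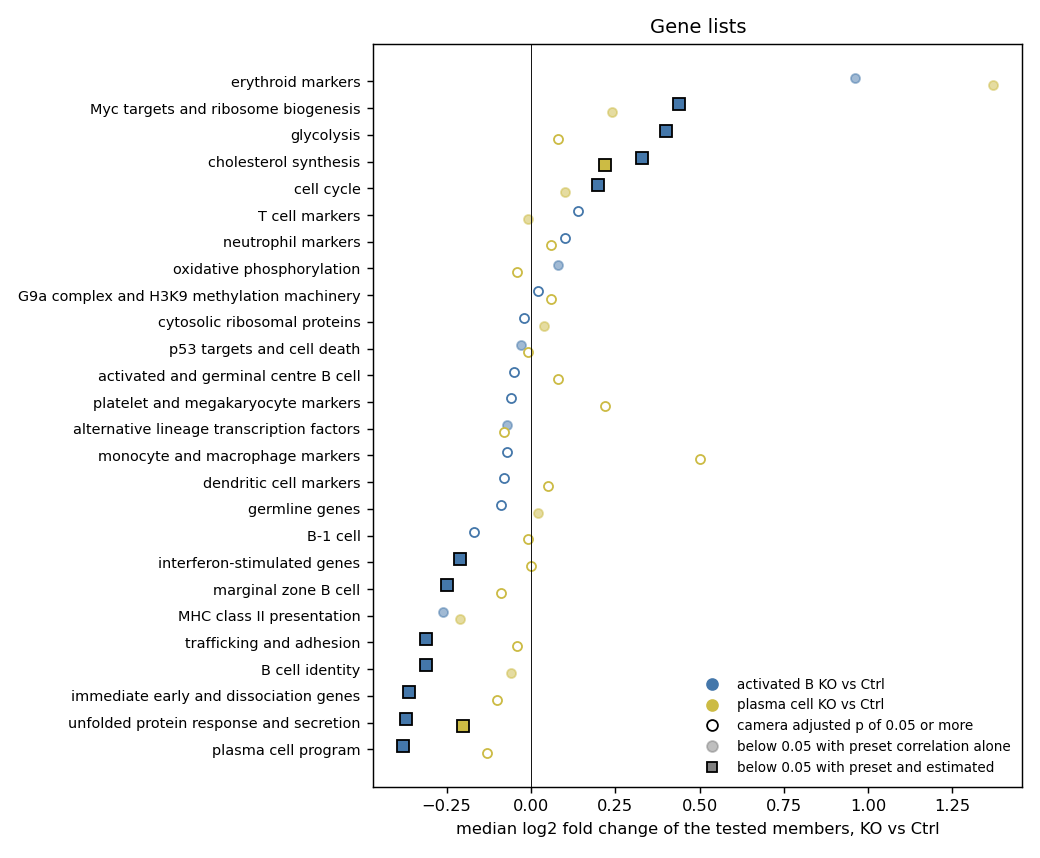
Median log2 change (KO over Ctrl) of the tested members of each gene list in activated B cells and plasma cells; open markers had a camera adjusted p of 0.05 or more, pale filled markers passed with the preset correlation alone, and squares passed with the estimated correlation as well. Unfolded protein response and secretion lay at -0.37 in activated B cells and -0.20 in plasma cells.

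Plasma cells of KO mice expressed several of the same genes, together with others that Ctrl plasma cells all but lacked. Wfdc15a (Entrez 68221, chromosome 2, 164198863 to 164200130), a protease inhibitor family member, was at 0.113 ± 0.195 in Ctrl and 27.3 ± 0.586 in KO (log2 change 4.68, SE 0.42, adjusted p = 4.3e-06). Akr1c13 was at 0.302 ± 0.408 and 24.6 ± 1.66 (adjusted p = 1.2e-04) and Afp at 1.66 ± 0.557 and 34.1 ± 3.9 (3.0e-05). Cd3e, a chain of the T cell receptor complex, was at 0.0767 ± 0.0667 and 8.71 ± 1.49 (0.001). Ly6c2 rose from 338 ± 72 to 1753 ± 86.7 and the serpin Serpinb7 from 5.7 ± 0.8 to 48.2 ± 5.65. Vpreb3, of the early B cell receptor, fell from 151 ± 13.7 to 35.7 ± 5.5 (log2 change -2.06, SE 0.17, adjusted p = 2.1e-06), and Apoe from 20.2 ± 10.1 to 3.52 ± 0.621 (0.004). Chchd10, of mitochondria, fell from 113 ± 1.6 to 54.6 ± 1.25 (3.4e-04), and D17H6S56E-5 from 475 ± 14.3 to 243 ± 12.8 (3.6e-05).

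In total 56 genes rose and 22 fell in plasma cell KO, with 750 at an unadjusted p under 0.05. The fit of their own libraries called 304 higher and 349 lower, including 77 of the 78. All 78 were called without the 6 naive libraries and with library weights. As in activated cells, the fits that left out a library kept the naive libraries and their larger spread. The count was 49 without Ctrl 1, 46 without KO 1, 49 without KO 3 and 46 without KO 4. The other named genes were Gml2, Gml, Akr1c12 and Sh2d1b1 among those that rose, and Ralgds, AW011738, Pdk2, Hvcn1, Pxdc1 and Tmem256 among those that fell. Akr1c12, AW011738, Pdk2 and Tmem256 lost their calls without any 1 of the 6 libraries (adjusted p up to 0.215, 0.191, 0.198 and 0.270), Sh2d1b1 without 5 (0.097) and Gml and Pxdc1 without 4 (0.123 and 0.132).

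Prdm1, Irf4 and Jchain had no called change in plasma cell KO. Prdm1 was at 103 ± 5.29 in Ctrl and 99 ± 4.99 in KO, Irf4 at 183 ± 14.3 and 182 ± 2.82, and Jchain at 6019 ± 321 and 5874 ± 364 (adjusted p = 1.000 for each). Xbp1 was not called either, but each KO library (1780, 2030 and 1910) lay below each Ctrl library (2270, 2640 and 2300). Of 36 plasma cell program genes 2 rose, Ly6c2 and Ly6c1, and 0 fell (3 and 0 adjusted over the list alone; median -0.13, camera adjusted p = 0.209). In the fit of their own libraries 3 rose and 6 fell (camera adjusted p = 0.015, and 0.603 with an estimated correlation). The unfolded protein response and secretion list was lower (median -0.20, adjusted p = 5.4e-17, and 0.010 with an estimated correlation), with 1 of 53 genes called, Herpud1, from 886 ± 74.2 to 563 ± 34.1, 5 adjusted over the list alone and 14 lower in the fit of their own libraries. Herpud1 lost its call without 2 of the 6 libraries (adjusted p up to 0.081). Cholesterol synthesis was higher (median 0.22, adjusted p = 1.2e-05, and 0.015 with an estimated correlation) with 0 of 24 genes passing limma over all genes or the list alone, and 8 higher in the fit of their own libraries. Estimated within the 6 plasma cell libraries alone, no list stayed under 0.05, with adjusted p from 0.223 upward. Of 40 Myc target genes 2 rose, Myc itself from 10.3 ± 1.22 to 18 ± 1.29 (adjusted p = 0.008) and Mybbp1a, and 1, Slc3a2, fell, or 4 and 1 adjusted over the list alone. Myc lost its call without 3 of the 6 libraries (adjusted p up to 0.073), Mybbp1a without 5 (0.227) and Slc3a2 without 5 (0.099). The Myc list had a median of 0.24 (camera adjusted p = 4.1e-09, and adjusted p = 0.051 with an estimated correlation). MHC class II genes were lower (median -0.21, 1.6e-05; adjusted p = 0.239 with an estimated correlation), with H2-Aa and H2-Eb1 called of 16 and 6 adjusted over the list alone. Both lie on chromosome 17 near Ehmt2. H2-Aa lost its call without 4 of the libraries (up to 0.199) and H2-Eb1 without 3 (0.219), and both did with RPKM as deposited (0.064 and 0.083).

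Other lists passed with the preset correlation alone. Erythroid markers had a median of 1.37 (adjusted p = 8.9e-06, and adjusted p = 0.051 with an estimated correlation) and a summed level of 2.24 ± 0.362 in Ctrl and 26.4 ± 31.6 in KO. Of 6, Car2 was called, from 1.51 ± 0.37 to 6.52 ± 1.2, and 3 were called adjusted over the list alone. T cell markers (median -0.01, camera direction up, 0.021; adjusted p = 0.315 with an estimated correlation) had Cd3e alone called of 9, and 2 adjusted over the list alone. Germline genes (median 0.02, 0.014; adjusted p = 0.336 with an estimated correlation) had Wfdc15a and Tuba3b called of 15, and 3 adjusted over the list alone. B cell identity (median -0.06, 0.021; adjusted p = 0.511 with an estimated correlation) had Vpreb3 and Cd79a lower and Cr2 higher of 37, and 3 lower and 2 higher adjusted over the list alone. Cell cycle (median 0.10, 0.012) and ribosomal proteins (0.04, 0.027) had 0 members passing limma, and adjusted p = 0.320 and 0.723 with an estimated correlation. Left-out libraries ended these calls: B cell identity and ribosomal proteins without 3 of the 6 (adjusted p up to 0.588 and 0.695), cell cycle without 2 (0.181), T cell markers without 2 (0.058) and germline genes without 1 (0.075). Of the single genes, Cr2 lost its call without any 1 of the 6 libraries (up to 0.174), with quantile normalization and with a replicate block. Tuba3b did without 5 (0.096), with a pseudocount of 0.1 and with a replicate block. The remaining lists were not called. Among pathways these were interferon-stimulated genes (median 0.00, adjusted p = 0.711), glycolysis (0.08, 0.070), oxidative phosphorylation (-0.04, 0.170), trafficking (-0.04, 0.170), immediate early genes (-0.10, 0.236) and p53 targets (-0.01, 0.940). Among cell types and lineages they were activated and germinal centre genes (0.08, 0.131), marginal zone genes (-0.09, 0.348), B-1 genes (-0.01, 0.276), alternative lineage factors (-0.08, 0.130), and monocyte (0.50, 0.276), neutrophil (0.06, 0.943), dendritic cell (0.05, 0.743) and platelet markers (0.22, 0.345).

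The KO responses of activated B cells and plasma cells shared genes. Both had 15 genes higher, where independent lists of these sizes would share 0.24 (one-sided exact hypergeometric p = 4.1e-24). Among them were Akr1c13, Akr1c12, Akr1e1, Afp, Ly6c2, Gml2, Car2 and Wfdc15a. Both had 13 genes lower, against 0.30 for independent lists (exact hypergeometric p = 1.6e-19). Among them were Apoe, Cd79a, Vpreb3, Herpud1, D17H6S56E-5 and the inhibitory Fc receptor Fcgr2b. Another 2 genes, Btg1 and Gpr171, fell in activated B cells and rose in plasma cells. Both lists came from 1 fit with 1 spread per gene, so genes of low spread are called more readily in both. The tested genes also include 2385 that averaged under 1 RPKM in both cell types. Independent lists ignore both points, so these p-values are too small. In separate fits of their own libraries 118 higher and 175 lower genes were shared, against 16 and 21 for independent lists. The log2 changes correlated across all genes with Pearson's r = 0.47 and Spearman's rho = 0.39, which is descriptive, since genes are not independent replicates. The labels do not say whether activated and plasma cell libraries of the same number came from the same mouse; if they did, differences between mice would be shared, and independent lists would understate the overlap without a KO effect. The number shared among higher genes was 9 without activated Ctrl 1 and 8 without activated Ctrl 4, KO 1 or KO 3. That among lower genes was 7 without plasma cell Ctrl 1, Ctrl 3 or KO 4 and 8 without KO 1 or KO 3.

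**Figure D3:**
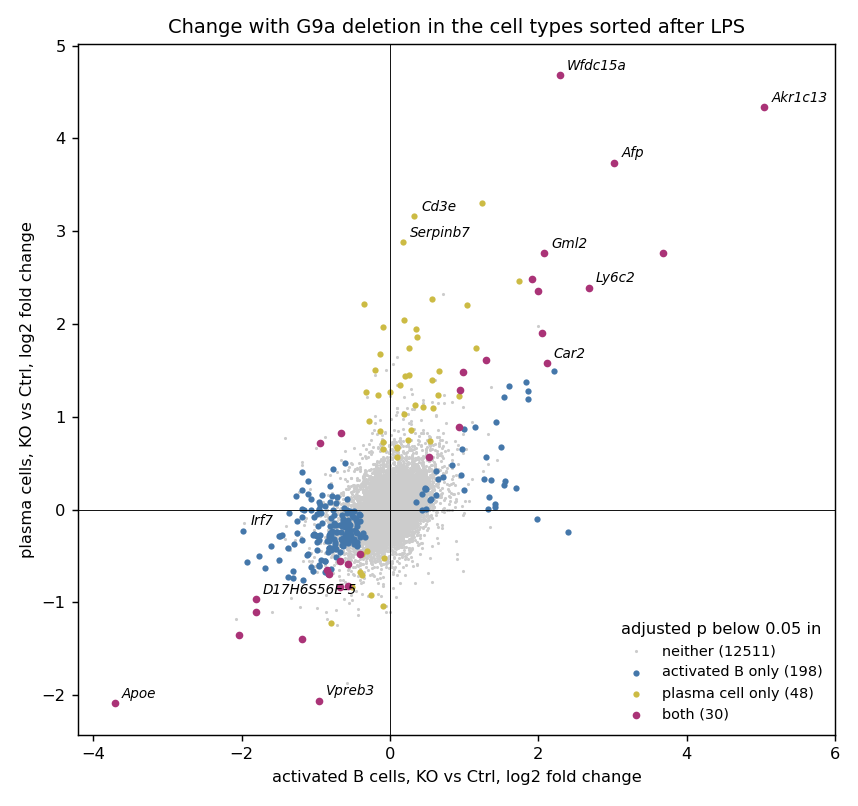
Log2 change (KO over Ctrl) of each tested gene in activated B cells (horizontal) and plasma cells (vertical), coloured by whether it was called in activated B cells (198 genes), in plasma cells (48), in both (30) or in neither. Akr1c13 and Afp lay high and Apoe low on both axes.

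In naive B cells no single gene was called in KO when their own spread was used. The fit of all libraries called 269 higher and 655 lower genes, with 3072 at an unadjusted p under 0.05, while limma on the 6 naive libraries alone called 0, with 898 at an unadjusted p under 0.05 and a smallest adjusted p of 0.363. Simulated data with this spread, smoothed by level, gave 755 false calls of 941 in the fit of all libraries. The named genes are given as values: Oas1c, of the interferon-induced synthetase family, was at 1.26 ± 1.11 in Ctrl and 8.66 ± 2.68 in KO (log2 2.22, adjusted p = 0.002, and 0.399 in the fit of their own libraries). The odorant receptor Olfr720 was at 9.09 ± 1.25 in Ctrl and 1.1 ± 1.39 in KO (log2 -2.47, 8.6e-04, and 0.363), and Olfr661 at 5.75 ± 3.26 in Ctrl and listed at 0 in KO. The others were Rgs13, Dreh, Paqr8, Rps4l, Ackr2, Zfp846, Msantd4, Pate1 and Cptp, higher in KO, and Odf1, Olfr812, Olfr705, Reg2, Olfr432, Olfr18, Serpinb9 and Olfr1043, lower in KO, each with an adjusted p of 0.363 or more in the fit of their own libraries. Among the 655 lower genes 15 were odorant receptors, of 54 tested, and 46.9% of the 655 averaged under 1 RPKM in activated and plasma cells of both genotypes, against 18.7% of tested genes. The share of higher genes was 29.1%, and 52.3% after quantile normalization. The count was 1706 without Ctrl 2 and 2436 without KO 2, the shallowest library by estimate.

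By list in naive KO, camera on the fit of all libraries called oxidative phosphorylation (median 0.12, adjusted p = 8.6e-06), unfolded protein response and secretion (0.11, 4.7e-04) and ribosomal proteins (0.08, 4.7e-04), each with adjusted p = 0.712 with an estimated correlation. Their members called were 4 of 60, 4 of 53 and 0 of 68 (5, 4 and 0 adjusted over the list alone), and 0 in the fit of their own libraries. The other 23 lists had adjusted p-values of 0.052 or more. Camera in the fit of their own libraries called the same 3 lists (1.3e-06, 9.5e-04 and 1.1e-04), B cell identity (0.015) and Myc targets (0.025), all higher, and with an estimated correlation there no list was under 0.680. Activated and naive KO shared 6 higher genes (1.1 for independent lists, exact hypergeometric p = 9.1e-04) and 3 lower genes (8.9, p = 0.994). Naive and plasma cell KO shared 3 higher (1.2, exact p = 0.114) and 0 lower (1.1, p = 1.000). These used the naive calls of the fit of all libraries, and 0 were shared with those of their own. The 6 became 1 or 2 without any 1 of the activated libraries, and 14 and 11 without naive Ctrl 1 and KO 2. The correlations of log2 changes across genes were 0.04 and 0.

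**Figure D4:**
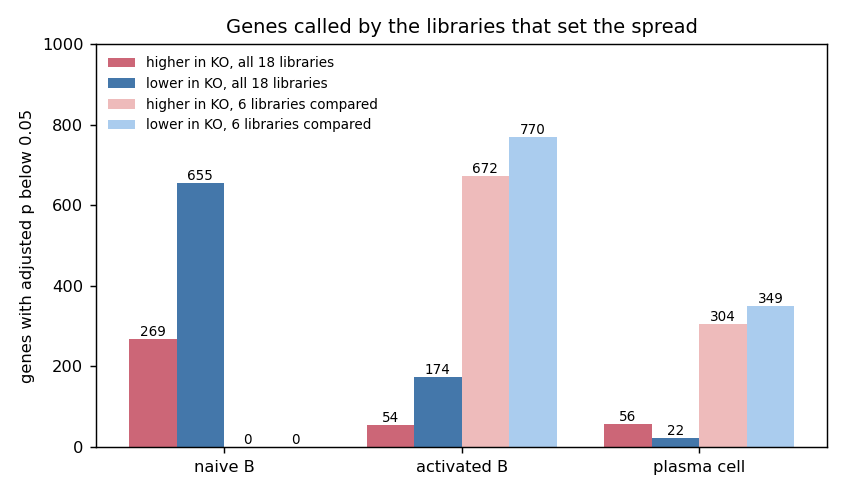
Number of genes called higher and lower in KO in each cell type, by limma on all 18 libraries and on the 6 libraries of the cell type. The 924 calls in naive cells became 0 and the 228 in activated B cells became 1442.

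Whether KO effects differ between cell types was tested directly. From activated B cells to plasma cells the KO effect was higher for 20 genes and lower for 0, with 416 at an unadjusted p under 0.05 and 160 and 48 called in the fit of their own libraries. Jchain (difference 1.32, SE 0.16, adjusted p = 0.001), S1pr1 (1.40, 0.003) and Btg1 (1.66, 0.002) fell in activated KO, where plasma cell KO had log2 changes of -0.04 for Jchain and 0.72 for Btg1. The actin-binding Tmsb4x (1.39, 5.9e-05) and the GTPase Gimap3 (1.22, 0.003) rose in plasma cell KO. The number of genes was 9 to 13 without activated Ctrl 1, Ctrl 3, Ctrl 4, KO 3 or KO 4, or plasma cell Ctrl 1, Ctrl 4, KO 1, KO 3 or KO 4. Against naive cells, the effect differed for 335 genes in activated B cells and 177 in plasma cells, with 2179 and 2062 at an unadjusted p under 0.05, and 24 and 23 in the fit of their own libraries. In that fit all 10 genes picked by the rule for each difference passed, among them Afp, Apoe and Jchain in activated B cells and Wfdc15a and Vpreb3 in plasma cells, while with library weights 3 and 7 of the 10 did. Leaving out a library moved the count of 335 to 166, 150, 108, 152, 134 and 176 for activated Ctrl 1, Ctrl 3, Ctrl 4, KO 1, KO 3 and KO 4, and to 749 and 1191 for naive Ctrl 2 and KO 2. It moved the count of 177 to 79, 72, 61, 79 and 65 for plasma cell Ctrl 1, Ctrl 3, KO 1, KO 3 and KO 4, and to 306, 576, 327 and 1130 for naive Ctrl 1, Ctrl 2, KO 1 and KO 2. The shares of higher genes, 51.6% and 68.4%, were 39.1% and 54.3% after quantile normalization.

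Genes of Ctrl differentiation were also taken as sets, in which single genes moved while the medians stayed near 0. In activated KO, 1784 genes that rise from naive to plasma cells had a median change of 0.004 (camera adjusted p = 0.389) and 3995 that fall had -0.056 against 0.014 for other genes (0.016; adjusted p = 0.453 with an estimated correlation). Of the rising genes 9 were called higher and 66 lower, and of the falling genes 15 and 65. Over all 12787 tested genes 54 were called higher and 174 lower. The rising set thus held a larger share of the lower calls than of the tested genes, as did the falling set to a lesser degree. This excess was not tested. The falling set was not called without Ctrl 1 (-0.016), Ctrl 4 (-0.002) or KO 1 (-0.030). In plasma cell KO, genes rising and falling from naive to activated cells had medians of 0.060 and -0.005 (adjusted p = 0.077 and 0.982), and the former passed with RPKM as deposited (0.106, adjusted p = 0.023). Called members there were 2 higher and 2 lower of the rising set and 19 and 5 of the falling set. In naive KO the genes rising and falling from activated to plasma cells had medians of -0.045 and 0 (0.369 and 0.081). Single libraries decided some of these: a call appeared without activated Ctrl 4 (rising genes, -0.016), plasma cell Ctrl 1 (rising, 0.067) or KO 4 (rising, 0.056, and falling, -0.089), and naive Ctrl 1, Ctrl 2 or KO 2 (falling, 0.012, 0.022 and 0.004).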

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

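The tests with the MHC class II genes left out, the counts near Ehmt2 in the fit of their own libraries, the use of the naive fit of their own libraries (a fit chosen beforehand) as a test of spread, the share of silent genes and the plasma cell share were chosen after the results were seen. The tests of genes near Ehmt2, of the scaling and of the shallow library were planned first. What drew attention to each result here was a KO effect that differed between cell types in the limma test of the difference itself. That test called 335 genes between activated and naive B cells, 20 between plasma cells and activated B cells, and 177 between plasma cells and naive B cells. The fit of their own libraries called 24, 208 and 23, and library weights gave 6, 636 and 19. The counts of 335 and 177 thus rest on a shared estimate that understates the naive spread. The genes named below passed in both fits, while the list differences from naive cells are given for the fit of all libraries alone.

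Between activated and naive B cells the KO effect on Tmem97 differed by 1.64, on Gml2 by 2.08, on Bag2 by 2.44, on Afp by 3.65 and on Aurkb by 1.35. In the other direction D17H6S56E-5 differed by -1.92, Jchain by -1.69, Kcnk5 by -1.54, Apoe by -3.62 and Dnajb9 by -1.31. By list the medians differed by -0.36 for the plasma cell program, -0.48 for unfolded protein response and secretion and -0.39 for immediate early genes. Between plasma cells and activated B cells the differences were 1.39 for Tmsb4x, 1.32 for Jchain, 1.66 for Btg1, 1.40 for S1pr1 and 1.22 for Gimap3. The list medians differed by 0.37 for the plasma cell program, 0.14 for unfolded protein response and secretion, 0.19 for marginal zone genes, -0.26 for glycolysis, 0.22 for trafficking and 0.30 for immediate early genes. With the correlation estimated in the fit of their own libraries, none of these 6 was called (adjusted p = 0.129, 0.349, 0.238, 0.238, 0.108 and 0.108). Between plasma cells and naive B cells Gml2 differed by 2.76, Clec2g by 3.17, Wfdc15a by 5.21 and Afp by 4.37, while Vpreb3 differed by -2.07, D17H6S56E-5 by -1.08, Cd79a by -0.93, Mcfd2 by -1.23 and Sdf2l1 by -0.78. The unfolded protein response and secretion list differed by -0.30 there.

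Relabelling libraries within each cell type gave as many genes in 3 of 100 splits for activated against naive B cells (335, highest other 644), the real split included. The same number did for plasma cells against activated B cells (3 of 100, with 20 genes and highest other 364), a share under 0.05 for both. The splits were drawn at random in each cell type, and only the real split was not drawn again. A drawn split could keep the genotype groups of 1 cell type, or keep both and exchange the labels of 1. Other splits mixed the genotypes, which removes the KO effects along with their difference. A small share therefore cannot show that the KO effects differ between the cell types. For plasma cells against naive B cells 5 of 100 did (177, highest other 533), and chance is not excluded. A split that exchanges the genotype labels in 1 cell type adds the effects of both cell types and gave 361, 364 and 191 genes, which is a structure of the design. The highest other count for plasma cells against activated B cells, 364, equals the count of this exchange and is no measure of chance. In each comparison of 2 groups, 3 libraries against 3 make 10 splits, too few for a share under 0.05. There the real counts and the highest of the other splits were 228 and 0 for activated KO, 78 and 0 for plasma cell KO, 7465 and 0 and 4196 and 0 for the Ctrl steps, 7127 and 0 and 4235 and 0 for the KO steps, with 1 split as large in each. For naive KO they were 924 and 1881, with 2 splits as large. In naive cells another split thus called more genes than the genotypes.

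Within 10 Mb of Ehmt2 lay 9% of genes called in plasma cells (7 of 78: D17H6S56E-5, H2-Aa, H2-Eb1, Tapbp, Fgd2, Btnl2 and Cyp4f16) against 2.1% of tested genes (Fisher's exact p = 0.001, and 0.018 without the MHC class II genes), or 3.2% in the fit of their own libraries (21 of 651, 0.029). In activated B cells the share was 1.8% (Fisher's exact p = 0.694, and 0.831 without the MHC class II genes), or 2.5% in the fit of their own libraries (36 of 1441, 0.132), which argues against position as the source of most changes there. Sequence carried with the floxed allele, which every KO library and no Ctrl library holds, may account for part of the calls near the gene in plasma cells. Of the 7 genes, D17H6S56E-5 alone was also called in activated KO, whose libraries hold the same allele. Fgd2 changed by 0.95 in plasma cells and by -0.28 in activated B cells (limma adjusted p = 0.464), and the others had the same sign in both. Loss of G9a stays open for the same genes, since the design does not part it from the allele. D17H6S56E-5, 83 kb from Ehmt2, fell in both cell types but not in naive cells, whose KO libraries hold the same allele (109.6 ± 15.5 in Ctrl and 117.9 ± 10.2 in KO, limma adjusted p = 0.547).

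The naive KO calls are a candidate artifact of spread. A fit of the 6 naive libraries left 0 calls, where the fit of all libraries had 924, in line with a shared estimate that understated the naive spread. Of the genes called lower, 46.9% were near silent in the other cell types, against 7.4% of those called higher and 18.7% of tested genes. Low signal that differs between libraries and loss of G9a cannot be told apart for those genes, since median odorant receptor levels ran from 1.69 to 7.07 RPKM between single naive libraries. An effect of G9a in naive cells stays open and was not shown here.

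Secretory and plasma cell genes were lower in activated KO. A smaller share of Sdc1-expressing plasma cells in the sorted gate is argued against. If all Sdc1 RNA of activated Ctrl came from such cells, the group means would put their share at 0.64%. Losing a share of 0.64% would give a median of 6.5% of the fall over 21 genes, and 18% for the gene most affected. The median of the unfolded protein response list was -0.37 with RPKM as deposited and -0.35 without the shallow KO 3 library, so neither scaling nor that library accounts for it. What stays open is a lower share of early plasmablasts with little Sdc1, which could carry the same genes, and a lower expression per cell. Loss of G9a itself, the biology that the design names, stays among the open explanations as untested.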

How the results depend on the processing

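Chosen after the data were seen were the fit without the 6 naive libraries, the overlaps in the fit of their own libraries, the alternatives for Ehmt2 beyond scaling and pseudocount, and leaving out libraries for lists, overlaps, signatures and Ehmt2. Counts are of genes called by limma and are listed in the order naive, activated and plasma cell KO, the steps, then the differences between cell types, where a setting moved them by more than 1.5 times. Outside the replicate block, replicate numbers were not used to pair samples. Same-numbered libraries of both genotypes correlated, after group means were removed, at -0.001, -0.189 and -0.122 in naive, -0.212, -0.165 and 0.07 in activated and 0.068, 0.195 and 0.312 in plasma cells. Same-numbered activated and plasma cell libraries correlated at -0.008, 0.122 and 0.154 in Ctrl and 0.055, -0.192 and -0.025 in KO. Unless the construction shows it, the cause was not tested.

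A minimum of 2-fold, which is stricter by construction, gave 456, 75 and 49 genes for KO, 4178 and 2193 for the Ctrl steps and 3656 and 2178 for the KO steps. Its overlaps were 4 (lower, activated with plasma), 2 and 0 (naive with activated) and 2 (naive with plasma, higher). A pseudocount of 0.1 gave 436 for naive KO, and 206 and 102 for the differences of activated and of plasma from naive cells. A filter at 5 RPKM, with fewer genes tested, gave 472 for naive KO, 4963 for activated against naive in Ctrl and 115 for the difference of plasma from naive cells, which was 116 with quantile normalization. The fit of their own libraries gave 0, 1442 and 653 for KO, 6430 and 6744 for plasma against activated in Ctrl and KO, and 24, 208 and 23 for the differences. Its overlaps were 118 and 175 for activated with plasma and 0, 0 and 0 with naive. Library weights gave 0, 2446 and 1641 for KO, 7111 and 7507 for plasma against activated, and 6, 636 and 19 for the differences, and Ehmt2 passed in plasma cells at -0.28. A replicate block gave 486 and 50 for KO, 6584, 3663 and 6690 for plasma against activated in Ctrl, activated against naive in KO and plasma against activated in KO, and 172, 178 and 69 for the differences. Without the 6 naive libraries the counts were 1850 and 788 for activated and plasma cell KO, 6663 and 6781 for plasma against activated and 208 for their difference. With an estimated correlation the falling signature in activated KO (-0.056) was no longer called, and with RPKM as deposited the rising one in plasma cell KO (0.106) was.

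Leaving out 1 library at a time gave 880 to 2436, 90 to 165 and 46 to 52 genes for KO, 6347 to 7533 and 3535 to 3622 for the Ctrl steps, and 5959 to 7508 and 3536 to 3660 for the KO steps. The differences ranged over 108 to 1191, 9 to 16 and 61 to 1130 (activated from naive, plasma from activated, plasma from naive). Overlaps were 8 to 11 higher and 7 to 12 lower for activated with plasma, 1 to 14 and 0 to 9 for naive with activated, and 1 to 9 and 0 to 1 for naive with plasma. Ehmt2 changed by -0.39 to 0.12 in naive, -0.07 to 0.12 in activated and -0.35 to -0.23 in plasma cells. Signature medians were -0.016 to 0.02 and -0.15 to -0.002 in activated KO (rising, falling), 0.038 to 0.081 and -0.089 to 0.065 in plasma cell KO, and -0.079 to -0.033 and -0.046 to 0.022 in naive KO. Lists whose direction turned, by median or by the test, were ribosomal proteins in plasma cell KO without Ctrl 4 (-0.02) and KO 3 (0; range -0.02 to 0.1) and monocyte markers there without KO 4 (range -0.29 to 0.77). In the difference of plasma from activated cells they were ribosomal proteins without plasma cell Ctrl 4 (range 0.01 to 0.11) and monocyte markers without plasma cell KO 4 (range -0.33 to 0.74). From activated to plasma cells in Ctrl, p53 targets (-0.34) turned by fry. Without the 6 naive libraries the lists that lost their calls were p53 targets (adjusted p = 0.084), alternative lineage factors (0.069) and erythroid markers (0.058) in activated KO, and germline genes (0.058), B cell identity (0.147) and ribosomal proteins (0.119) in plasma cell KO. Another 3 lost theirs in the steps from activated to plasma cells and 2 in the difference between these cell types. Among the named genes of activated and plasma cell KO, 239 kept their side of the threshold with RPKM as deposited and 231 with quantile normalization. It was kept by 226 with a pseudocount of 0.1, 220 with a replicate block and 208 at 2-fold. These counts include genes called in neither setting, whose direction was not compared. Calls were lost by 6, 9, 18, 23 and 39 of the named genes, and no called gene turned direction under these settings. Leaving out each library of the cell type in turn ended 166 calls of these genes, counted once per library left out. By the depth estimates the shallowest naive library had 1.64 M reads and activated KO 3 had 2.68 M, so that values of genes near 1 RPKM would rest on few reads there.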

Other observations

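The neighbour test was chosen after the changed genes had been seen, as were the genes named in this part. Further genes were higher in KO. Gtsf1, a partner of the piRNA pathway that silences transposons in germ cells, was at 0.529 ± 0.424 in activated Ctrl and 4.96 ± 0.506 in activated KO (n = 3 each; log2 change 1.99, limma adjusted p = 0.013). In plasma cells it was at 0.258 ± 0.446 and 5.36 ± 1.66 (2.36, 0.006). The aldo-keto reductase Akr1e1 went from 6.27 ± 0.628 to 13.4 ± 1.19 in activated B cells (0.99, 0.028) and from 2.08 ± 0.651 to 7.49 ± 1 in plasma cells (1.48, 0.002). In plasma cells the C-type lectin Clec2g went from 1.01 ± 0.393 to 8.69 ± 1.75 (2.27, 4.3e-05), and Il10ra, a chain of the interleukin-10 receptor, from 1.44 ± 0.525 to 4.83 ± 0.757 (1.27, 0.002). Gimap3 and Gimap4, GTPases of lymphocyte survival, went from 3.42 ± 0.405 to 10.3 ± 1.97 (1.34, 4.6e-06) and from 9.36 ± 0.817 to 15.5 ± 0.889 (0.67, 0.019). Tmsb4x, which binds actin monomers and was among the most abundant of these, rose from 570 ± 46.7 to 1339 ± 115 (1.23, 8.4e-07).

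A pair of genes moved in opposite directions in the cell types. Btg1, which holds back proliferation, fell from 77.1 ± 9.66 to 39.6 ± 3.03 in activated KO (log2 change -0.94, limma adjusted p = 0.003) and rose from 2.25 ± 0.521 to 4.39 ± 1.25 in plasma cell KO (0.72, 0.040). The receptor Gpr171 fell from 27.6 ± 2.01 to 17.2 ± 2.94 (-0.66, 0.045) and rose from 8.32 ± 0.333 to 15.5 ± 1.09 (0.82, 0.020).

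Several genes that rose lie beside each other, among them Akr1c13, Akr1c12 and Akr1e1 on chromosome 13 and Gml, Gml2, Ly6c1 and Ly6c2 on chromosome 15. The hypothesis that neighbouring genes respond together was tested by counting changed genes with another changed gene within 500 kb, against 10000 random sets of tested genes of the same size. The higher genes prompted the test, so their counts, 11 in plasma cells and 7 in activated B cells, restate what had been seen and support nothing. Without the genes named above, the higher genes had 4 in plasma cells (random median 2, 95th percentile 6, one-sided permutation p = 0.271) and 2 in activated B cells (2 and 6, p = 0.636). Sets of 49 and 48 genes are too small to exclude a shared control.

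Genes lower in activated B cells, which had not prompted the test, had 43 with a neighbour (random median 24, 95th percentile 34, one-sided permutation p = 0.002). A control shared by neighbours may account for this, as a hypothesis. The random sets do not account for gene families, whose members share both position and regulation, for gene-dense regions that are expressed together, or for reads shared between close paralogs, and these were not tested apart.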
